A study of Mus musculus with 4 samples.

How the data were processed

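Single cells of tumour-draining inguinal lymph nodes were profiled with the 10x Genomics 3' version 3 chemistry in 4 C57BL/6J mice, 2 of a control group and 2 of a treated group. The deposited matrix gives raw counts of unique molecular identifiers (UMIs) for 31053 genes in 30824 cell barcodes, with no normalisation. Per the file headers the counts were made with cellranger 5.0.0, and per the labels the genome build was mm10. The 47794614 entries were checked to be whole numbers of at least 1. Whether reads were evened out between libraries when the authors combined them is not stated. The labels give approximately 2000 cells per sample and approximately 80k reads per cell, whereas the deposited matrix holds 7002, 6978, 7013 and 9831 barcodes in libraries 1, 2, 3 and 4. The total counts of these libraries were 39589629, 39733183, 40339336 and 53643414 UMIs.

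Each barcode ends in a library number from 1 to 4, and nothing in the deposited tables ties a library number to a mouse or a group. No library was therefore assigned to a group, and the treated against control comparison is not analysed here. The design fixed in advance set out what to do in this case: libraries were described one by one, never averaged as replicates and never tested against each other, and genes were compared between cell classes within each library. The library is taken to be a separate cell suspension from 1 mouse, which the deposited tables do not state. On that reading the spread between libraries holds the treatment, the mouse and the preparation together.

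Barcodes with at least 300 genes and at most 10% of UMIs from mitochondrial genes were kept. Doublets were scored in each library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 0.8% per 1000 cells, and 105, 120, 228 and 474 called doublets were removed. The 25169 cells left were scaled to 10000 counts per cell and log-transformed. Clustering used the 2000 genes most variable within libraries plus cell type markers, without T cell receptor and immunoglobulin variable segments and without comparison-list genes that are not markers. It used 30 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with seed 1 and no integration of libraries. Calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and plots were drawn with matplotlib 3.10.9.

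Clusters were named only from marker sets of 23 cell classes fixed in advance. A name needed a mean marker log2 fold of at least 0.8 over all other cells, at least 3 detected markers, at least 1 of them among the 10 genes most enriched in the cluster, no more markers of another class there, and a mean below 1.2 for markers of every other lineage. A cluster with Cd3e in at least 50% of its cells could only be named as a T cell class, and 1 with both coreceptors, the second in at least 20% of cells, stayed unnamed. The marker sets were fixed before the data were examined, and these naming thresholds were not. Of the 26 clusters, 18 were named, in 13 classes, and 8 stayed unnamed. No cluster met the rule for conventional type 2 dendritic cells (cDC2), so 4 of the contrasts fixed in advance were not made. The 6 that could be made were kept, and 3 contrasts among the dendritic cell and monocyte classes were added after the classes had been seen.

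Raw counts were summed per class and library and scaled to counts per 1000000 UMIs of the class in that library (CPM). A gene was called higher or lower when its ratio between both classes was at least 1.5-fold in the same direction in every library with at least 10 counts of it over both classes, with at least 3 such libraries. The call is a rule and not a significance test. Calls were counted over 20 gene lists fixed in advance. Named genes were, per contrast and list, up to 4 called genes with the largest ratio of summed CPM with a prior count of 1, to a limit of 28 genes per contrast. Btk, Ido1, Ido2, Foxp3, Itgae, Batf3, Ly6c2 and Zbtb46 were named for every class. For the libraries, the rule took in each of the 4 largest named classes (B-like, CD8 T-like, CD4 T-like and regulatory T-like) the 5 genes with the largest ratio of highest to lowest library, after adding 10 CPM, among genes with at least 50 CPM in 1 library. Ratios are given without a prior, and no fold is given against a class with 0 counts. Confidence intervals are exact at 95%: Clopper-Pearson for shares and for the split of counts between classes, and Poisson for CPM. They cover counting error only. A count of 0 allows up to 3 counts. Gene positions were taken from the GENCODE vM21 annotation of the same build by Ensembl identifier.

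The fold rule was tested on simulated data, drawn from the real class totals with a dispersion of 0.05 and 200 genes changed in each contrast. Of unchanged genes it called between 0.19% and 2.08% in 8 contrasts and 6.62% in NK-like against CD8 T-like cells. It recovered between 69.1% and 97.0% of genes changed 4-fold and between 21.9% and 46.5% of genes changed 2-fold. An added requirement, chosen after the contrasts of very unequal classes had been seen, counts a library only where equal levels would give at least 5 counts in each class or the smaller class has at least 10. With it at most 0.777% of unchanged genes were called. The simulation drew both classes from a pooled profile, without RNA of other lineages and without a shift in composition. Rates in the real contrasts may therefore be higher.

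Alternatives for the class shares were no cell filter, a stricter filter of at least 800 genes and at most 5% mitochondrial UMIs, Leiden resolutions 0.5 and 2, doublets kept, 4000 variable genes, and list genes allowed in the clustering. Alternatives for the contrasts were a mean over cells, at least 50 counts, at least 2-fold, TMM scaling with edgeR 4.0.16 in R 4.3.3, doublets kept, the stricter filter, cells thinned to 1500 UMIs, and leaving out each library. Thinning left out cells with fewer than 1500 UMIs, which were 147, 141, 123 and 177 of the clustered cells of libraries 1 to 4. The median macrophage-like cell, at 1102 UMIs, was below that limit, so thinning also selects cells. The added requirement on counts and a run without cells that carry transcripts of another lineage were chosen after the data had been seen. That run leaves out cells with Cd79a in T and NK classes, with Cd3e in B classes, and with either in the other classes.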

Results

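Tumour-draining inguinal lymph nodes were profiled cell by cell in a study of inflammatory dendritic cells under inhibitors of the kinase BTK and of the tryptophan-degrading IDO pathway. Mice carried B16F10 tumours, a transplantable melanoma, in both thighs. The control group held 2 untreated mice. The treated group held 2 mice that drank indoximod, an inhibitor of the IDO pathway, at 2 mg/ml from day 9, received ibrutinib, a BTK inhibitor, at 350 ug per day, and received the alkylating agent cyclophosphamide at 150 mg/kg on day 10. Nodes of all mice were collected 48 hours after the cyclophosphamide. Each mouse is taken to have given a separate library. The deposited barcodes carry only the library numbers 1 to 4, so the libraries are not assigned to mice or groups. The effect of treatment is therefore not analysed here.

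Libraries 1, 2, 3 and 4 held 7002, 6978, 7013 and 9831 barcodes, where the labels give approximately 2000 cells per sample and 80k reads per cell. Their total counts were 39589629, 39733183, 40339336 and 53643414 UMIs, with medians of 4830, 4848, 5002 and 4672 UMIs per barcode. After filtering and removal of doublets, 5562, 5638, 6107 and 7862 cells entered the clustering. Intervals in the text cover counting error only, and the libraries are not replicates of a known group. A log2 ratio is followed in parentheses by the lowest and highest library, or by its counting interval where a library had no counts in 1 of the classes. Calls over all genes tested are given with each contrast. A list called at about the share of all genes is not read as a result about that list.

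The nodes were mostly made up of lymphocytes in every library. B-like cells took a median of 35.2% of the clustered cells over the libraries (34.1% to 37.2%), CD8 T-like cells 22.2% (21.9% to 23.5%) and CD4 T-like cells 21.1% (19.7% to 22.8%). Regulatory T-like cells, which restrain other T cells, took 3.04% (2.79% to 3.18%) and gamma-delta T-like cells 1.60% (1.47% to 1.78%). Mature dendritic cell (DC)-like cells, named from maturation markers such as Ccr7 and Fscn1, took 1.76% (1.47% to 2.43%). Whether they had reached the node from tissues or matured in it was not measured. Macrophage-like cells took 1.36% (1.06% to 1.65%), monocyte-like cells 0.544% (0.442% to 0.834%) and conventional type 1 DC (cDC1)-like cells 0.400% (0.242% to 0.503%). NK-like cells took 0.345% (0.252% to 0.393%), plasmacytoid DC-like cells 0.319% (0.102% to 0.485%) and neutrophil-like cells 0.0764% (0.0360% to 0.160%). Germinal centre B-like cells, the dividing B cells of an ongoing antibody response, differed most between libraries: 161 cells or 2.89% (exact 95% interval 2.47% to 3.37%) in library 1, 169 or 3.00% (2.57% to 3.48%) in library 2, 7 or 0.115% (0.0461% to 0.236%) in library 3 and 6 or 0.0763% (0.0280% to 0.166%) in library 4. At clustering resolution 0.5 the shares were 3.85%, 3.81%, 0.573% and 0.7504%. Plasmacytoid DC-like shares were 0.485% (0.320% to 0.706%), 0.408% (0.259% to 0.611%), 0.229% (0.125% to 0.384%) and 0.102% (0.0439% to 0.200%) in libraries 1 to 4. The 2459 cells of the unnamed clusters took a median of 9.83% (8.74% to 11.2%), and 80.4% of them carried Cd3e. They held a cluster of 680 cells with Izumo1r, Maf, Icos and Sh2d1a among its 10 most enriched genes and Cd3e in 93.1% of cells. Izumo1r was the only regulatory T marker among these genes, and the best-scoring T cell marker set was that of CD4 T cells. They also held a cluster of 278 cells with Mki67 among its 10 most enriched genes and Cd3e in 91.0%, a cluster of 391 cells with Nr4a1 there and Cd3e in 90.5%, and a cluster of 637 cells with Ccl5 there and Cd8a in 71.1%. These clusters were singled out after their values were seen, and the CD4 T-like and CD8 T-like classes below are without them. Among the other unnamed clusters, 253 cells were enriched in Hbb-bs and Ighg2c, and 43 in C1qa with Cd79a in 100% of cells. A cluster of 89 cells had Cd3e in 95.5% and Cd79a in 97.8% of cells. The melanoma markers Dct, Pmel, Tyrp1 and Mlana were among the 10 most enriched genes of 88 cells. Too few melanoma markers were detected there to name this cluster.

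Median depth differed between classes, from 1102 UMIs per cell in the macrophage-like class to 12406 in the germinal centre B-like class. Transcripts of other lineages were found in every class: Cd79a, a B cell receptor gene, had a UMI in 14.5% of regulatory T-like cells (median 5118 UMIs) and 5.32% of CD4 T-like cells (median 5391 UMIs). Cd3e, a T cell receptor gene, had a UMI in 22.8% of monocyte-like cells (median 10867 UMIs) and 2.25% of B-like cells (median 3791 UMIs). With the stricter cell filter the median macrophage-like share was 0.513% and the plasmacytoid DC-like share 0.146%, and the cDC1-like share with list genes in the clustering was 0.697%.

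**Figure D1:**
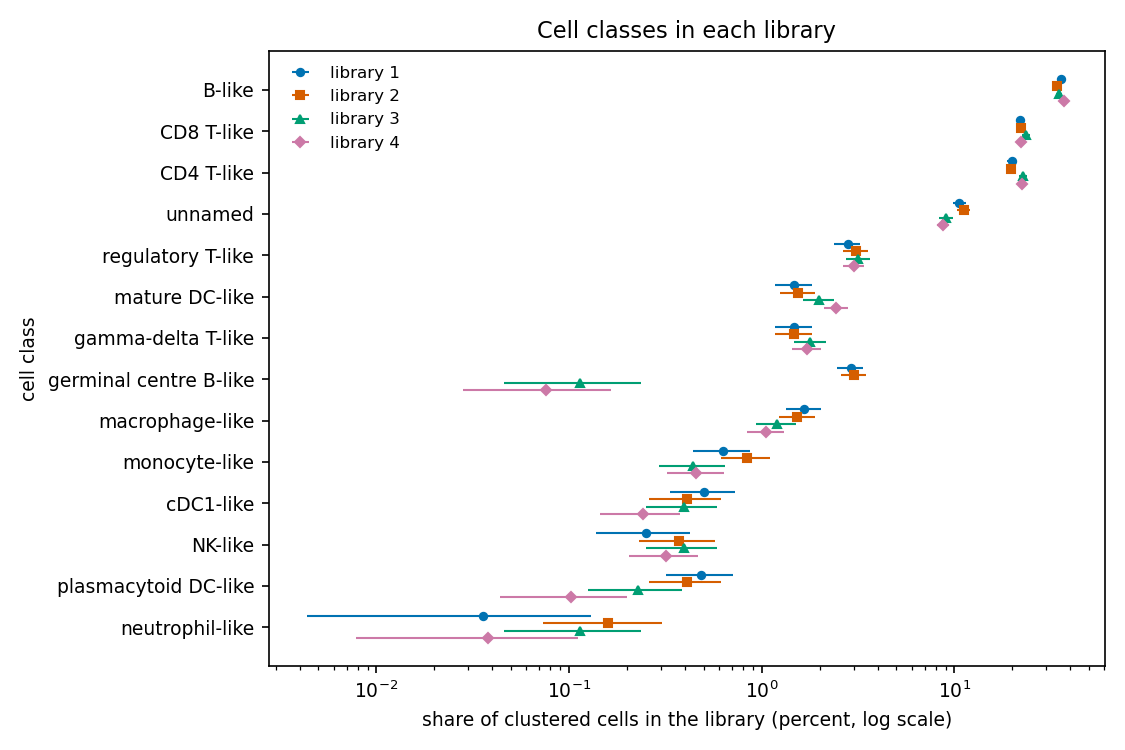
Share of clustered cells in each cell class (horizontal axis, percent on a log scale) in each of the 4 libraries, with exact 95% intervals as horizontal bars. B-like cells lie between 34.1% and 37.2%, and germinal centre B-like cells between 0.0763% and 3.00%.

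Where the drug targets are transcribed was read from the counts of Btk and of the IDO genes in each named class. Btk, the target of ibrutinib, was transcribed mainly in B-like cells, at 118 CPM (126, 122, 113 and 114 in libraries 1 to 4), and in germinal centre B-like cells, at 87.7 CPM (exact 95% interval 80.0 to 95.8). Its level was 78.6 CPM (33.9 to 155) in neutrophil-like cells, of which there were 21, 42.1 CPM (33.0 to 52.9) in monocyte-like, 39.6 (25.4 to 58.9) in plasmacytoid DC-like, 35.0 (21.7 to 53.5) in cDC1-like, 33.3 (21.3 to 49.5) in macrophage-like, 17.4 (14.0 to 21.4) in mature DC-like and 13.6 (10.5 to 17.4) in regulatory T-like cells. Cd79a was found in 28.6% of neutrophil-like, 15.2% of monocyte-like, 8.33% of plasmacytoid DC-like, 9.57% of cDC1-like, 10.8% of macrophage-like, 10.6% of mature DC-like and 14.5% of regulatory T-like cells. CD4 T-like cells had 0.574 CPM (0.334 to 0.918) and CD8 T-like cells 0.919 (0.647 to 1.27). A Btk UMI was found in 37.7% of B-like cells (median 3791 UMIs) and in 0.316% of CD4 T-like cells (median 5391 UMIs), which should lack it. B-like cells had Cd79a in 99.8%. Btk was in 35.9% of monocyte-like and 25% of plasmacytoid DC-like cells, above the shares with Cd79a there. This argues against B cell RNA as the main source of Btk in both of these classes. The Btk share was 28.6% in neutrophil-like, 13.9% in mature DC-like and 13.8% in cDC1-like cells. It was 6.29% in macrophage-like and 4.88% in regulatory T-like cells, below the shares with Cd79a. For these other classes the shares do not decide the source. Btk (ENSMUSG00000031264) lies on chromosome X from 134542336 to 134583570 in build mm10.

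Ido1, which encodes the tryptophan-degrading enzyme that gives the IDO pathway its name, was barely detected. It had 9 counts, in 9 of 481 mature DC-like cells, and 21 counts, in 16 of 343 germinal centre B-like cells. No UMI of Ido1 was found in the other named classes. It was in 0 of 8952 B-like cells, which allows up to 0.0335% of them to carry a UMI at a median of 3791 UMIs. A result of 0 of 145 monocyte-like cells allows a level of up to 1.73 CPM. The unnamed clusters were not examined for Ido1. The mature DC-like level was 1.74 CPM (0.798 to 3.31), with 4.32, 2.11, 0.735 and 1.04 in libraries 1 to 4. The germinal centre B-like level was 3.81 CPM (2.36 to 5.83), with 2.78, 4.95, 0 and 0 CPM in libraries 1 to 4, of which libraries 3 and 4 held 7 and 6 such cells. Its paralog Ido2 had 4 counts in mature DC-like and 1 in germinal centre B-like cells. Ido1 (ENSMUSG00000031551) lies on chromosome 8 from 24584136 to 24597009, and Ido2 (ENSMUSG00000031549) next to it from 24531892 to 24576333.

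Among genes that mark dendritic cell states, Batf3, a transcription factor needed for cDC1 development, was at 225 CPM (212 to 239) in mature DC-like and 213 CPM (178 to 254) in cDC1-like cells, and at 47.9 CPM (38.1 to 59.3) in monocyte-like cells. Zbtb46, a transcription factor of conventional DCs, was at 48.1 CPM (42.3 to 54.4) in mature DC-like, 40.0 (25.6 to 59.5) in cDC1-like and 17.9 (12.1 to 25.4) in monocyte-like cells. Itgae, which encodes the integrin CD103, was at 113 CPM (100.3 to 126) in gamma-delta T-like, 70.7 (63.4 to 78.6) in regulatory T-like and 38.5 (36.6 to 40.5) in CD8 T-like cells, against 16.7 (7.99 to 30.6) in cDC1-like and 2.13 (1.06 to 3.82) in mature DC-like cells. Ly6c2, a surface marker of inflammatory monocytes, was highest in plasmacytoid DC-like cells among the named classes, at 2428 CPM (2305 to 2555). In monocyte-like cells its level was 243, 238, 2446 and 2626 CPM in libraries 1 to 4, over 35, 47, 27 and 36 cells. Foxp3, the regulatory T cell transcription factor, was at 231 CPM (218 to 245) in regulatory T-like cells and 0.911 (0.600 to 1.33) in CD4 T-like cells. Its UMIs were in 63.1% of regulatory T-like cells and in 0.235% of B-like cells, which should lack it, at medians of 5118 and 3791 UMIs.

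**Figure D2:**
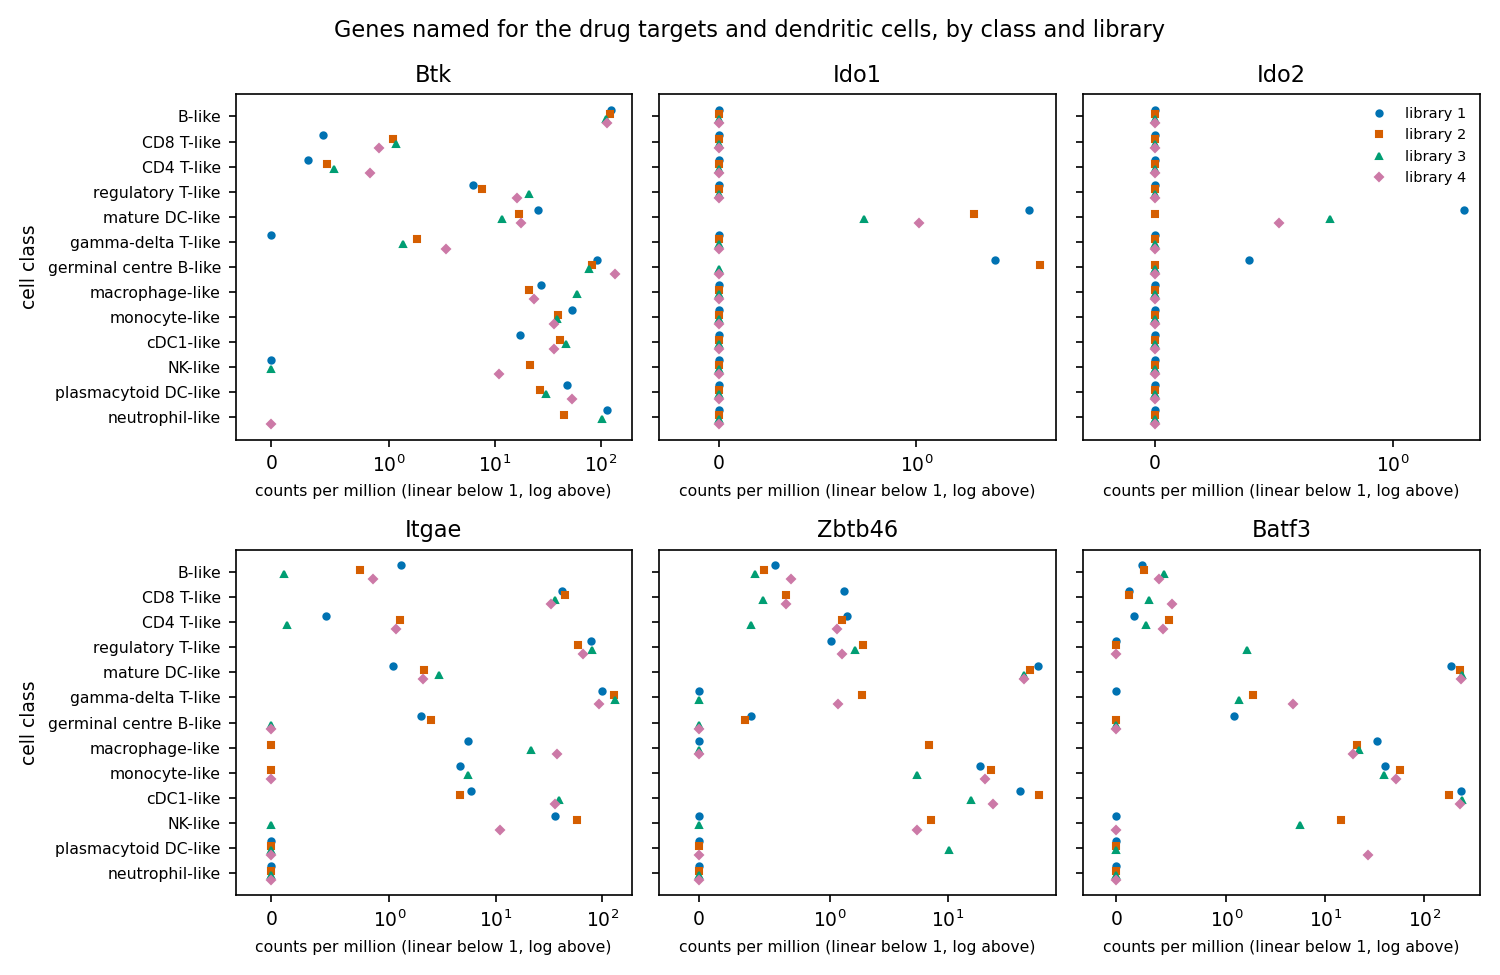
Level of 6 of the genes named for the drug targets and dendritic cells (horizontal axes, CPM, linear below 1 and logarithmic above) in each named cell class and library, with 1 point per library. Btk is at 113 to 126 CPM in B-like cells and reaches 136 CPM in the germinal centre B-like cells of library 4. Among the named classes, Ido1 is above 0 in mature DC-like and germinal centre B-like cells only.

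Regulatory T-like against CD4 T-like cells differed in checkpoint, cytotoxic and activation genes: 95 of 271 list genes were higher and 5 were lower. Calls over all 10198 genes tested were 973 higher and 189 lower. All 9 tested genes of the T cell checkpoint and exhaustion list were higher, among them Lag3, an inhibitory receptor, at a log2 ratio of 6.16 (counting interval 4.96 to 7.65), and Entpd1, an ectonucleotidase that degrades ATP, with 69 counts against 3 at 7.14 (counting interval 5.53 to 9.45) and at 8.36 without library 4. Of the cytotoxic effector list 7 of 9 were higher, including Gzmb, which encodes granzyme B, at 8.40 (counting interval 7.03 to 10.29) and at 7.59 without library 4. Itgae was higher at 6.51 (5.55 to 9.21) and Ccr6, a chemokine receptor, at 6.35 (5.58 to 7.12). Lef1, a transcription factor of naive T cells, was lower at -1.74 (-1.86 to -1.58).

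Against this CD4 T-like class, which lacks the unnamed T cell clusters with Izumo1r, Nr4a1 or Mki67, 8 of 12 receptor-induced immediate early genes were higher, with Irf4 at 4.33 (3.65 to 5.37), as were 7 of 10 costimulation and checkpoint ligands, with the maturation marker gene Cd83 at 5.29 (4.69 to 6.43), and 8 of 19 interferon-gamma response genes. The aryl hydrocarbon receptor gene Ahr was higher at 4.00 (3.52 to 4.41), and 3 of 5 genes of its list were. Of the cell cycle lists 5 of 16 S phase and 6 of 8 G2 and M phase genes were higher, with the proliferation marker Mki67 at 3.77 (3.45 to 4.04). Higher were also 6 of 11 inflammatory dendritic cell genes, 3 of 8 follicular helper and migration genes, 4 of 30 type I interferon genes, 3 of 15 amino acid stress genes, with Eif4ebp1 at 1.24 (0.95 to 1.84), 4 of 16 p53 and DNA damage genes, 2 of 15 dissociation stress genes, with Dusp1 at 2.02 (1.68 to 2.34), 1 of 15 MHC class I genes, H2-Q6 at 1.23 (1.06 to 1.34), and 3 of 18 glycolysis genes, while 1 other glycolysis gene was lower. As 973 of all 10198 genes tested were higher and 189 lower, low counts such as 4 of 30 or 1 of 15 say little about their lists. None of 20 oxidative phosphorylation genes was called, and 4 of 10 naive and homing genes were lower. MHC class II had 10 of 11 genes higher and the BTK and B cell receptor pathway 10 of 18, and these lists depended on cells with B cell RNA. Without the cells that carry Cd79a, 3 of 11 and 3 of 13 were higher, Cd74, the MHC class II invariant chain gene, went from 4.23 to 1.41, and Btk from 4.57 to -1.18. In that run 1 of 4 tryptophan and AhR genes, 3 of 7 G2 and M phase genes and 5 of 8 costimulation ligands were higher, and Kmo, which encodes an enzyme of tryptophan breakdown, went from 3.51 to -0.79. TMM scaling moved the median of all genes by -0.33 (log2), and 77 list genes were then higher and 11 lower.

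CD8 T-like against CD4 T-like cells differed in cytotoxic genes and in single genes of other lists: 27 of 271 list genes were higher and 14 lower. Calls over all 10946 genes tested were 377 higher and 333 lower. Of the cytotoxic effector list 7 of 8 genes were higher, among them Nkg7, a granule protein gene, at a log2 ratio of 6.51 (6.30 to 6.91), and Cxcr3, a chemokine receptor of effector and memory cells, at 4.92 (4.56 to 6.10). Fasl, the death receptor ligand gene, was lower, with 9 counts against 160 at -4.59 (-5.98 to -3.41) and at -5.37 without library 4. Itgae was higher at 5.63 (4.83 to 8.07) and Cd160, a receptor of cytotoxic cells, at 3.49 (3.14 to 4.56). Haao, an enzyme of tryptophan breakdown, was higher at 4.18 (3.94 to 4.99), as the only called gene of 7 in its list.

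Lower genes included Cd200, an inhibitory ligand, at -1.79 (-1.94 to -1.66), Pdcd1, which encodes PD-1, at -1.65 (-2.96 to -1.23), the immediate early gene Nr4a1 at -1.23 (-1.69 to -0.77), Gpr183, an oxysterol receptor that guides cells in the node, at -0.96 (-1.08 to -0.91), and Itga6 at -0.72 (-0.83 to -0.63). Of the type I interferon list 2 genes were higher and 3 lower of 30, with Mx1 at 1.53 (1.40 to 1.96) and Ifi44 at -1.37 (-1.46 to -1.14). Of the MHC class II list H2-Oa was higher at 1.96 (1.56 to 2.39) and H2-DMa at 0.74 (0.66 to 0.84), 2 of 11 genes. Of the interferon-gamma list 3 of 19 were higher, and none of 17 glycolysis and 20 oxidative phosphorylation genes was called. With cells thinned to 1500 UMIs and shallower cells left out, the called list genes numbered 26 instead of 41.

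B-like against CD4 T-like cells showed the antigen-presenting and BTK programme of B cells: 91 of 287 list genes were higher and 41 lower. Calls over all 11309 genes tested were 1966 higher and 1248 lower. Of the BTK and B cell receptor pathway 17 of 19 genes were higher, with Blnk, the adaptor next to BTK, at a log2 ratio of 7.77 (7.09 to 10.24) and Btk itself at 7.69 (7.08 to 8.67). All 11 tested MHC class II genes were higher, with Cd74 at 7.72 (7.24 to 8.68) and H2-DMb2, a peptide-loading chain, at 7.54 (7.09 to 8.68). Of the tryptophan catabolism and AhR list 7 of 9 were higher, with Kynu, an enzyme of kynurenine breakdown, at 906 counts against 3 and 7.85 (counting interval 6.30 to 10.13). Of the naive and homing list 2 of 10 were higher and 6 lower, with the T cell transcription factor genes Tcf7 at -5.83 (-6.30 to -5.58) and Lef1 at -5.79 (-6.59 to -5.50).

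Of the costimulation and checkpoint ligands 7 of 10 were higher and 1 lower, with Cd83 at 6.62 (5.77 to 7.46). The interferon-gamma list went both ways, with 4 higher and 8 lower of 18, and its member Ciita, the master regulator of MHC class II genes, was at 7.09 (6.99 to 7.44). Il12a, an interleukin subunit gene, was higher at 7.05 (6.18 to 7.80), the follicle-homing receptor gene Cxcr5 at 6.09 (4.97 to 8.20), Irf4 at 4.51 (3.83 to 5.25), and the type I interferon gene Mx1 at 2.69 (2.43 to 2.78), in a list with 7 higher and 3 lower of 30 and, under TMM scaling, 5 higher and 5 lower. Lower genes also included Tox, a transcription factor of T cell exhaustion, at -5.75 (-6.62 to -5.44), and Trib3, a stress kinase gene, at -2.71 (-4.42 to -2.14). None of 20 oxidative phosphorylation genes was called. TMM scaling moved the median of all genes by -0.11, with 85 list genes higher and 49 lower.

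Germinal centre B-like against other B-like cells were higher in cell cycle genes and lower in interferon genes: 66 of 283 list genes were higher and 85 lower. Calls over all 10665 genes tested were 1028 higher and 1429 lower. All 18 tested G2 and M phase genes were higher, with Hmmr, a spindle gene, at a log2 ratio of 9.37 (8.70 to 9.95) and Mki67 at 8.75 (7.63 to 9.92), as were 14 of 19 S phase genes, with Dtl at 5.16 (3.12 to 6.62). Of oxidative phosphorylation genes 13 of 20 were higher, with Uqcr10 at 1.44 (0.88 to 1.47), and 7 of 20 under TMM scaling, while the glycolytic enzyme gene Tpi1 was higher at 2.34 (1.55 to 2.70), in a list with 7 higher and 1 lower of 18. Of the type I interferon list 21 of 30 were lower and of the interferon-gamma list 10 of 18, with Irgm1, an immunity-related GTPase gene, between -3.14 and -1.91 in the single libraries. With enough counts asked of the smaller class 10 of 16 and 4 of 5 were lower.

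Genes of recirculating cells were lower in germinal centre B-like cells, 6 of 10 in their list, with Klf2, a transcription factor of quiescent lymphocytes, at -3.74 (-6.24 to -3.13). Gpr183, which keeps B cells outside the follicle centre, was lower at -3.25 (-4.08 to -3.14). MHC class II genes were lower in 8 of 11 cases, with Ctss, a protease gene, at -1.58 (-1.68 to -1.15), MHC class I genes in 8 of 15, and costimulation ligands in 6 of 10, with Icosl at -2.93 (counting interval -3.32 to -2.56). The BTK pathway had 3 of 19 genes lower, among them Bank1, a B cell adaptor gene, at -2.38 (-2.92 to -1.86), and 6 of 16 amino acid stress genes were higher. Libraries 3 and 4 held 7 and 6 germinal centre B-like cells but many B-like cells, so ratios of summed counts also hold differences between libraries, and with enough counts asked of the smaller class 111 list genes were called, 59 higher and 52 lower. Under that requirement the costimulation list had 4 lower and 1 higher of 6, and the amino acid stress list 2 higher of 4. TMM scaling moved the median of all genes by -0.16, with 52 list genes higher and 97 lower, and thinned cells gave 32 higher and 70 lower.

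NK-like against CD8 T-like cells, a class without the unnamed cluster with Ccl5 and Cd8a, were higher in effector genes: 50 of 265 list genes were higher and 20 lower. Calls over all 10309 genes tested were 876 higher and 798 lower. Of the cytotoxic effector list 9 of 10 were higher, with Gzmb at a log2 ratio of 11.87 (8.83 to 13.72) and at 11.28 without library 4. The protease inhibitor gene Serpina3g was higher at 6.47 (5.63 to 7.29) and Id2, a transcription regulator of innate lymphocytes, at 3.62 (3.30 to 4.11). Of the naive and homing list 3 of 10 were lower, with Lef1 at -2.87 (-4.57 to -2.28), and the metabolic kinase gene Pdk1 was lower at -2.69 (-3.29 to -2.23).

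Tnfrsf9, an activation receptor gene, was higher in NK-like cells at 5.18 (3.32 to 5.83) and Cd160 at 3.15 (2.37 to 3.99). The type I interferon list had 5 of 30 genes lower and none higher, and the interferon-gamma list 5 of 19 lower and 1 higher, which became 4 of 13 lower, and 1 lower and 1 higher of 10, with enough counts asked of the NK-like class. The class held 84 cells, and on simulated data the rule called 6.62% of unchanged genes here, so calls on low counts are left without a fold. With enough counts asked of the NK-like class 33 list genes were higher and 10 lower, while TMM scaling moved the median of all genes by -0.59 and gave 27 higher and 34 lower, and thinned cells gave 18 higher and 17 lower.

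**Figure D3:**
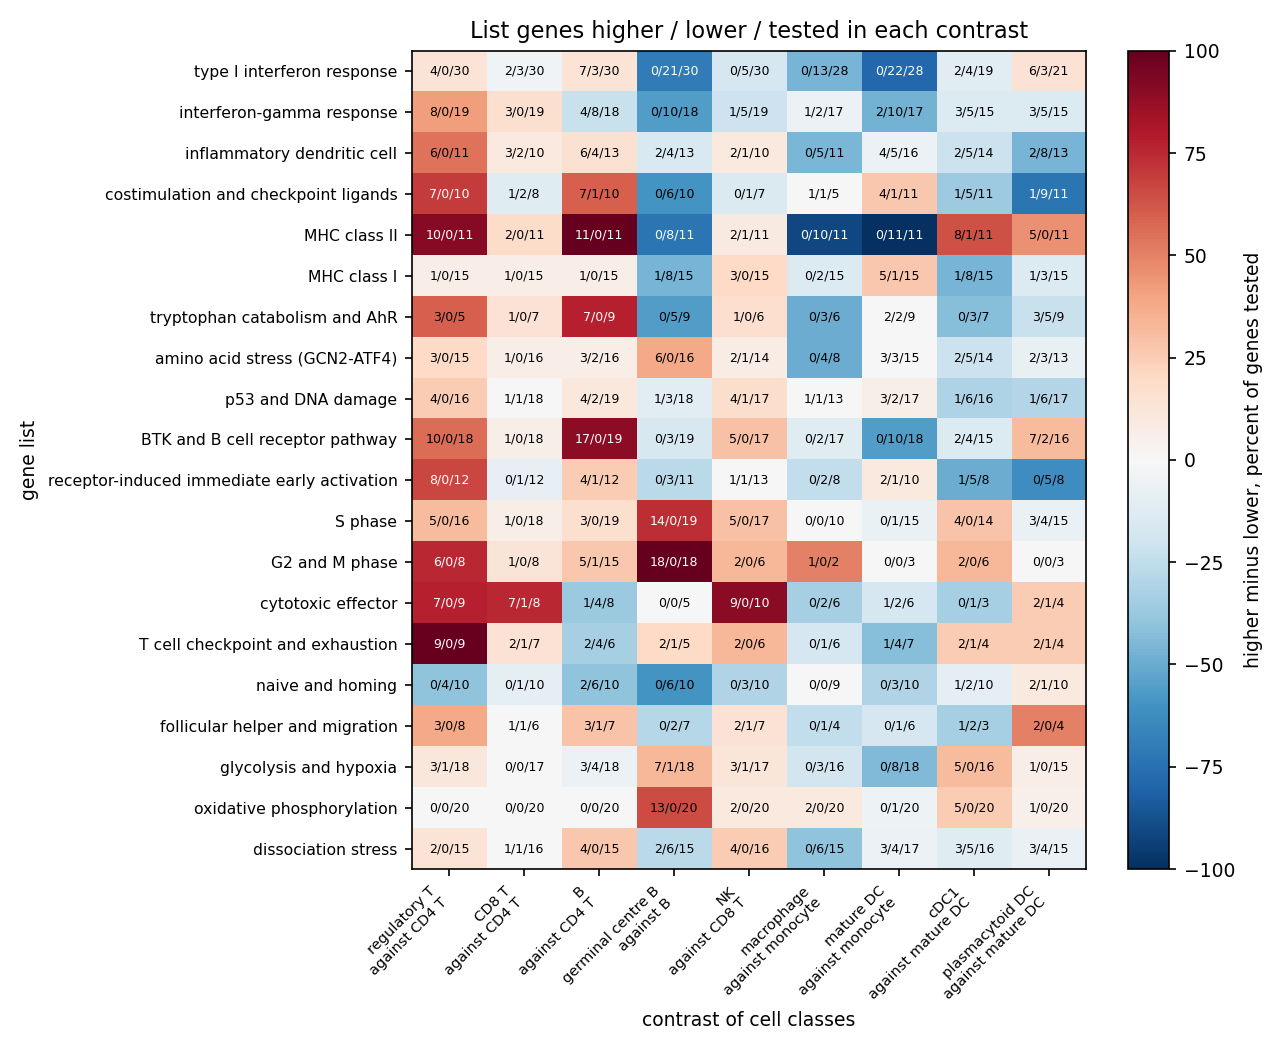
Number of genes higher, lower and tested by the 1.5-fold rule for each of the 20 gene lists (vertical axis) in each of the 9 contrasts of cell classes (horizontal axis), coloured by the genes higher minus the genes lower as a percent of the genes tested. The G2 and M phase list in germinal centre B-like cells (18 of 18 higher) and MHC class II in mature DC-like against monocyte-like cells (11 of 11 lower) lie at the ends of the scale.

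Macrophage-like against monocyte-like cells were lower in most called genes: 6 of 222 list genes were higher and 56 lower. Calls over all 6029 genes tested were 271 higher and 741 lower. Lower were 10 of 11 MHC class II genes, among them H2-Ab1, a class II chain gene, at a log2 ratio of -2.67 (-2.91 to -2.37), and 13 of 28 type I interferon genes, with Rsad2, an antiviral gene, at -2.74 (counting interval -3.54 to -2.03). The stress transcription factor gene Cebpb was lower at -2.16 (-2.61 to -1.52), in a list with 4 of 8 lower, and the fractalkine receptor gene Cx3cr1, high in patrolling monocytes, at -3.15 (-5.67 to -2.07). The respiratory chain gene Cox5a was higher at 1.47 (1.26 to 1.63), 1 of 2 called in a list of 20.

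Of the inflammatory dendritic cell list 5 of 11 were lower, with Cd40 at -2.50 (-3.49 to -1.28), and of the dissociation stress list 6 of 15, with Fos at -4.10 (-5.80 to -2.40). Fos was -3.47 without library 4 and -4.93 without library 2. BTK pathway genes were mostly not called, with 2 of 17 lower, among them Dapp1, an adaptor gene, at -2.21 (-2.41 to -1.95). The macrophage-like class had a median of 1102 UMIs per cell against 10867 in the monocyte-like class, and 22.8% of monocyte-like cells had a Cd3e UMI. A UMI of Zbtb46, a gene of conventional DCs, was in 16.6% of monocyte-like cells, and no cDC2 class was named. The monocyte-like class may therefore hold DCs. Its Ly6c2 level also differed between libraries, at 243, 238, 2446 and 2626 CPM in libraries 1 to 4. With the stricter filter, on both detected genes and mitochondrial share, 2 of 10 MHC class II genes were lower and 1 higher, and H2-Ab1 was -0.89, Cebpb -3.45 and Gbp3, an interferon-induced GTPase gene, -0.03 in place of 1.48.

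Mature DC-like against monocyte-like cells, a contrast added after the classes were seen, gave 29 of 263 list genes higher and 89 lower. Calls over all 8628 genes tested were 922 higher and 1380 lower. Cd3e was carried by 22.8% of the monocyte-like cells. A Ly6c2 UMI was in 52.4% of them, a Batf3 UMI in 29.0% and a Zbtb46 UMI in 16.6%. Their Ly6c2 level was 243, 238, 2446 and 2626 CPM in libraries 1 to 4. The median of their type I interferon list was -0.64, -0.74, 0.67 and 0.66 (log2 from the median library). Ratios of summed counts against this class therefore also hold differences between libraries. With no cDC2 class named, DCs within the monocyte-like class cannot be told apart from monocytes here. All 11 MHC class II genes were lower at the transcript level, with H2-DMb1 at a log2 ratio of -3.74 (-3.96 to -3.56) and Ciita at -3.29 (-3.46 to -2.95), and 22 of 28 type I interferon genes were lower, with Ifi204, a DNA sensor gene, at -5.79 (-7.22 to -4.81) and Irf7 at -4.25 (-5.53 to -2.17). The interferon-gamma list had 10 of 17 lower and 2 higher. Higher genes included Ccl5, a T cell-attracting chemokine gene, at 5.90 (4.88 to 6.97), Il15, a cytokine gene for NK and CD8 T cells, at 3.60 (2.42 to 4.65), the ligand gene Pvr at 3.64 (counting interval 2.74 to 4.71), Slc7a11, a cystine transporter gene, at 3.07 (2.13 to 4.95), and H2-Q6 at 3.14 (2.74 to 3.36).

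The BTK and B cell receptor pathway had 10 of 18 genes lower in mature DC-like cells and none higher, with the kinase gene Lyn at -3.23 (-3.69 to -2.95). Of glycolysis and hypoxia genes 8 of 18 were lower, with the hexokinase gene Hk2 at -4.10 (-5.64 to -2.66) and at -4.95 without library 1. The costimulation list had 4 of 11 higher and 1 lower, and the inflammatory dendritic cell list 4 of 16 higher and 5 lower, with Cxcl10, an interferon-induced chemokine gene, at -6.62 (-7.95 to -5.46), which was -5.92 without library 2 and -7.46 without library 4. Without cells of other lineages 9 of 11 MHC class II, 19 of 24 type I interferon and 7 of 14 BTK pathway genes were lower. With the stricter filter 6 of 11 MHC class II genes were lower, and TMM scaling moved the median of all genes by 0.32, with 49 list genes higher and 78 lower and the BTK pathway at 4 higher and 9 lower.

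cDC1-like against mature DC-like cells, also added, gave 44 of 232 list genes higher and 61 lower. Calls over all 7777 genes tested were 737 higher and 1354 lower. MHC class II genes were higher, 8 of 11 with 1 lower, among them H2-DMb1 at a log2 ratio of 3.91 (2.94 to 4.21) and H2-Ab1 at 3.53 (2.86 to 4.31). Ccl5 was lower at -7.91 (-9.07 to -7.07), Il4i1, an enzyme that breaks down tryptophan and other amino acids, at -5.70 (counting interval -6.91 to -4.72), and Cd83, a maturation marker, at -3.67 (-4.96 to -3.06). Il4i1 had 691 CPM in mature DC-like cells, and its ratio was -8.00 without library 2. Cxcl9, an interferon-gamma-induced chemokine gene, was higher at 6.41 (4.11 to 7.74) and at 5.35 without library 3.

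Costimulation and checkpoint ligands were lower in 5 of 11 cases and higher in 1, MHC class I genes lower in 8 of 15 and higher in 1, with H2-Q6 at -2.78 (counting interval -3.37 to -2.24), and p53 and DNA damage genes lower in 6 of 16 and higher in 1, with the cell cycle inhibitor gene Cdkn1a at -4.69 (counting interval -5.90 to -3.71) and at -5.39 without library 3. The lactate dehydrogenase gene Ldha was higher at 2.61 (2.00 to 2.80) and the respiratory gene Sdhb at 1.72 (1.36 to 2.17), in lists with 5 of 16 and 5 of 20 genes higher and none lower. Irf7 was higher at 2.39 (1.56 to 4.55). The cDC1-like class held 94 cells with a median of 2580 UMIs, and with enough counts asked of it 30 list genes were higher and 50 lower. TMM scaling moved the median of all genes by -0.26, with 36 higher and 65 lower.

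Plasmacytoid DC-like against mature DC-like cells, the last added contrast, gave 46 of 235 list genes higher and 57 lower. Calls over all 7973 genes tested were 1058 higher and 982 lower. Plasmacytoid DCs are the interferon-producing DC type. Of the costimulation and checkpoint ligands 9 of 11 were lower and 1 higher, with Cd83 at 1 count against 1423 and a log2 ratio of -7.38 (counting interval -12.69 to -4.90), a count that came from library 1. The interferon regulator gene Irf7 was higher at 4.08 (3.79 to 5.49), in a list with 6 higher and 3 lower of 21 and, with the stricter filter, 2 higher and 4 lower of 19. Of the BTK and B cell receptor pathway 7 of 16 were higher and 2 lower. Kmo was higher at 7.07 (6.49 to 8.09).

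MHC class II genes were higher in 5 of 11 cases, with H2-DMb1 at 2.87 (2.63 to 3.30), and receptor-induced immediate early genes lower in 5 of 8, with Nfkbia, an inhibitor of NF-kappa-B, at -2.07 (-2.53 to -1.96). Mthfd2, a mitochondrial folate enzyme gene, was lower at -4.19 (-4.65 to -3.90), and Gbp5 and Slc7a11 had 0 counts against 525 and 425. The inflammatory dendritic cell list had 8 of 13 lower and 2 higher. The class held 72 cells, and with enough counts asked of it 28 list genes were higher and 33 lower, while TMM scaling moved the median of all genes by -0.50 and gave 33 higher and 81 lower. With the stricter filter 18 were higher and 50 lower.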

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

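The requirement of enough counts in the smaller class and the run without cells of another lineage were chosen after seeing the data, and the other alternatives were planned. Of 249 named log2 ratios with alternatives, 240 kept their sign in every alternative that gave a value, 159 shifted by over 1.5-fold in at least 1 alternative and 74 did so without 1 library. These ratios were not computed as a mean over cells, and the minimums on counts and fold do not change them. Of the median class shares 74 of 86 alternative values stayed within the counting intervals of the middle libraries, of the counts of list genes 100 of 116 stayed within 1.5 times, and of the ratios between libraries 30 of 40 stayed within their resampled counting interval. Another 48 alternative values of named genes were not given because of 0 counts, and germinal centre B-like cells gave no contrast under the stricter filter. The cause was not tested for any value below, except that thinning and count minimums leave fewer genes to test by construction.

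Under the stricter filter the median shares were B-like 24.5%, CD8 T-like 25.1%, CD4 T-like 18.5%, regulatory T-like 3.74%, mature DC-like 2.58% and macrophage-like 0.513%, and the plasmacytoid DC-like share was 0.146%. Without a cell filter they were CD8 T-like 18.8%, CD4 T-like 18.4% and regulatory T-like 2.63%. With list genes in the clustering CD4 T-like cells were 18.3% and cDC1-like cells 0.697%, and at resolution 0.5 cDC1-like cells were 0.679%. No macrophage-like class was named with 4000 variable genes, with list genes in the clustering or at resolution 0.5. At resolution 0.5 the germinal centre B-like shares of libraries 1 to 4 were 3.85%, 3.81%, 0.573% and 0.7504%.

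Thinning gave 55 called list genes in regulatory T-like against CD4 T-like cells, 26 in CD8 T-like against CD4 T-like, 35 in NK-like against CD8 T-like, 27 in macrophage-like against monocyte-like, 63 in mature DC-like against monocyte-like, 54 in cDC1-like against mature DC-like and 38 in plasmacytoid DC-like against mature DC-like cells. A minimum of 50 counts gave 57 in regulatory T-like, 31 in macrophage-like and 56 in plasmacytoid DC-like cells. The 2-fold limit gave 44 in NK-like, 41 in macrophage-like and 69 in cDC1-like cells. Enough counts in the smaller class gave 43 in NK-like and 61 in plasmacytoid DC-like cells, where the stricter filter gave 68.

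Signs turned for Btk (-1.18) and Kmo (-0.79) in regulatory T-like cells without cells of another lineage. In macrophage-like against monocyte-like cells they turned for Flt3 (1.10), Lag3 (3.68), Klrd1 (2.97) and Gbp3 (-0.028) under the stricter filter and for Kynu (0.16) after thinning. In mature DC-like against monocyte-like cells they turned for Mcm2 under the stricter filter (1.21) and after thinning (0.81), and for Lag3 under the stricter filter (1.99). Thinning moved the ratio of highest to lowest library in B-like cells for Hba-a1 (4.64), in CD8 T-like cells for Hbb-bs (13.1) and Hba-a1 (8.02), in CD4 T-like cells for Gm10076 (3.16) and Ifit1 (3.03), and in regulatory T-like cells for Hbb-bs (62.7), Hba-a1 (15.2), Hba-a2 (14.1), Hbb-bt (10.3) and Gzmb (3.11).

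No paired analysis was possible because the libraries are not tied to mice, and no treated mouse can be set beside a control mouse. The class contrasts, made within each library, were not tested over libraries, as fixed before the data were examined. The settings set out in advance for the treated against control comparison were not run because the libraries are not tied to mice: edgeR against DESeq2, no filter on low counts, a replicate block, leaving out single mice, and other denominators for the shares.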

Other observations

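The tests of the germinal centre share, the matched-cell and Xist tests and the test of whole male libraries for the Y-linked transcripts, and the scaling test of the interferon list were chosen only after the results had been seen. The groups of the libraries are not known, so no explanation by treatment was tested.

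Erythroid transcripts differed most between libraries among the genes taken by the rule. Hbb-bs, a beta-globin gene, was at 273, 234, 16.6 and 32.9 CPM in the B-like cells of libraries 1 to 4, at 132, 238, 6.34 and 19.6 in CD8 T-like cells, at 196, 177, 8.18 and 28.3 in CD4 T-like cells and at 131, 172, 5.69 and 2206 in regulatory T-like cells. The last value came from 3500 counts in 236 cells, and how they were spread over these cells was not examined. After thinning, the highest to lowest ratio in this class was 62.7 in place of 141. Gm10076 was at 167, 396, 283 and 504 CPM in CD8 T-like cells and at 150.5, 345, 251 and 433 in CD4 T-like cells. Gzmb was at 87.7, 5.69, 26.8 and 61.1 CPM in regulatory T-like cells.

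Interferon-stimulated genes were also among those taken by the rule. Irf7, which drives interferon transcription, was at 33.0, 28.8, 136 and 142 CPM in B-like cells, and Ifit3, an antiviral gene, at 41.1, 31.7, 138 and 139. Ifit3 was at 27.7, 24.4, 79.2 and 81.9 CPM in CD8 T-like and at 22.1, 20.8, 63.8 and 66.1 in CD4 T-like cells. The inflammatory monocyte marker Ly6c2, not taken by the rule but named in advance, was at 13.4, 11.9, 44.4 and 42.2 CPM in B-like cells. Its level was 346, 352, 407 and 400 CPM in CD8 T-like and 5.14, 3.66, 5.36 and 6.97 in CD4 T-like cells. In regulatory T-like cells it was 33.0, 10.4, 12.2 and 58.6 CPM.

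The germinal centre B-like share was 2.89%, 3.00%, 0.115% and 0.0763% in libraries 1 to 4, and 3.85%, 3.81%, 0.573% and 0.7504% at resolution 0.5. After each cell was thinned, 64 of 2115, 70 of 2071, 2 of 2110 and 2 of 2885 B-lineage cells carried at least 3 markers, and the highest share was 48.8 times the lowest, which argues against depth. Over all deposited barcodes with Cd79a the counts were 184 of 2838, 185 of 2697, 11 of 2691 and 17 of 4190, a ratio of 16.9, which argues against loss in the filter or the clustering. Treatment, mouse and preparation of the node stay open.

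Transcripts of 4 Y-linked genes were found in 4, 0, 408 and 530 cells of libraries 1 to 4, while Xist, which marks female cells, was found in at least 53.8% of the B-like, CD4 T-like and CD8 T-like cells of libraries 3 and 4, against whole libraries of male cells. The highest share of Y-positive cells in these classes was 11.7%, between the bounds set for and against that explanation. Of 252 cells with at least 2 Y-linked genes, 11.9% (exact 95% interval 8.18% to 16.6%) carried Xist, against 75.8% of matched cells of the same class, library and depth, which argues against free RNA as the main source. In libraries 3 and 4 Y-positive cells were 1.13% and 1.37% of B-like and 10.6% and 11.7% of CD4 T-like cells. They were 10.04% and 9.603% of CD8 T-like and 10.8% and 14.4% of regulatory T-like cells. Xist was in 70.7%, 72.2%, 55.03% and 53.8% of CD4 T-like cells of libraries 1 to 4. For CD8 T-like cells the values were 84.6%, 83.6%, 68.5% and 68.7%. For regulatory T-like cells they were 89.03%, 83.8%, 70.1% and 71.2%, and for B-like cells 84.2%, 84.97%, 83.2% and 83.04%. In these T-like classes Xist was thus lower in libraries 3 and 4, as male cells among female cells would give. The share of 11.9% lies just above the bound of 10% set in advance, so that explanation stays open.

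The type I interferon list had medians of -0.40, -0.39, 0.41 and 0.37 in the B-like cells of libraries 1 to 4 (log2 from the median library, with 10 CPM added, 30 genes) and of -0.64, -0.74, 0.67 and 0.66 in monocyte-like cells. In germinal centre B-like cells the medians were 0.02, 0.01, -0.32 and 0.18 over 12 genes, with 7 and 6 cells in libraries 3 and 4. The range of the oxidative phosphorylation list in B-like cells was 0.0473 of that of the interferon list, which argues against the scaling of library totals. After thinning the range was 1.04 of its value before, which argues against depth. Treatment, mouse and handling of the node stay open.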
